A study of Rattus norvegicus with 20 samples.

How the data were processed

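Liver RNA from 20 male rats was measured on Affymetrix arrays, with 1 array per rat. The rats had received isodecyl diphenyl phosphate (IDDP), an aryl phosphate ester used as a plasticiser and flame retardant, or the corn oil vehicle, and the groups were taken from the dose in the sample labels. The authors deposited a table of log2 intensities per probe set, normalised with RMA per the submitters' processing notes. The RMA version, and which arrays were normalised together, are not given in the sources used here. The table held 31099 probe sets and 20 arrays, and the medians of the arrays lay between 6.31 and 6.41 on the log2 scale. The number of arrays limits the precision: 5 control rats and 3 rats per dose. Raw array images, body and organ weights and other toxicological measures were not analysed here.

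The 57 Affymetrix control probe sets were left out of the tests, which covered 31042 probe sets with no filter on brightness. Gene symbols came from the annotation of the array. Of the tested probe sets, 20826 carried exactly 1 symbol, 436 carried several and 9780 are unnamed here. The probe sets with 1 symbol stood for 14217 distinct symbols, and 20758 of those probe sets were matched to the RefSeq annotation of the rat assembly GRCr8 by Entrez identifier, with 0 symbols updated. No gene was named from a probe set with several symbols.

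Each dose was compared with the controls in limma 3.58.1 under R 4.3.3. A linear model with 1 mean per dose group was fitted to all 20 arrays, with empirical Bayes moderation of the variances (14 residual and 5.75 prior degrees of freedom). Tests were two-sided, and p was adjusted by Benjamini and Hochberg over all tested probe sets with a threshold of 0.05. The same fit gave the contrasts of 1054.2 mg/kg with 527.1 and 66 mg/kg. A trend was fitted as the slope of the log2 value on the rank of the dose, from 0 to 5. The p-values measure spread between rats. Errors of a change are standard errors from the fit, errors of a group mean are standard deviations, and control means are over 5 rats and dose means over 3.

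These choices were made before the data were examined: the comparisons, the tests, the gene lists, the first set of alternatives and the rule for naming genes. For 1054.2 mg/kg the rule took the 12 largest rises and the 12 largest falls among probe sets past the threshold with exactly 1 symbol and with every treated rat on the same side of the control mean. For each lower dose and each contrast between doses it took the 5 largest in each direction, and for the trend the 5 of smallest p in each direction. Each gene was taken once, by its probe set of largest change, and symbols starting with LOC or RGD were counted and not named. From each list it took up to 4 members with the largest change at 1054.2 mg/kg among those past the threshold there, or the member with the largest change where none passed. The rule gave 89 genes. Of these, 25 had more than 1 probe set, and 0 had probe sets past the threshold in opposite directions. At 1054.2 mg/kg every probe set passed for 13 of the 25, some for 10 and none for 2.

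The 28 lists, written from general knowledge of rat liver, held 483 distinct measured genes, 21 of them in more than 1 list. They covered CAR and PXR targets, AhR targets, PPARalpha targets, NRF2 targets, cholesterol synthesis and uptake, fatty acid synthesis, bile acid synthesis and transport, cell cycle, acute phase and inflammation, the unfolded protein and ATF4 response, p53 targets, gluconeogenesis and glucose handling, the circadian clock, male-predominant and female-predominant liver genes, carboxylesterases and paraoxonases, glutathione transferases, pericentral and periportal hepatocyte genes, and markers of Kupffer cells and macrophages, neutrophils, T and NK cells, B cells, endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells and pancreas. Each gene was read from its probe set with the highest mean over all arrays, and lists with at least 5 measured genes were tested. Lists were tested with camera from limma at its preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. The mean of a list's genes per array, relative to the control mean, was compared by an exact permutation test over all 56 splits of the 8 arrays (two-sided, smallest possible p 0.0179). No list that passed at any dose changed the sign of its mean when array medians were centred or quantile normalization was applied again.

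RNA quality was read from the difference between the 3' and 5' control probe sets of beta-actin and GAPDH, averaged per array. Effects of the lower doses were compared with those of 1054.2 mg/kg by correlation across probe sets, with the 5 controls split between both comparisons over 20 ordered splits, and in 20 simulations with no effect. Alternatives were: dim probe sets left out (mean under log2 6.37, 15521 probe sets), 1 probe set per gene, medians centred, quantile normalization again, a variance trend with robust moderation, array weights, the replicate number as a block, only the groups compared, a change of at least 1.5-fold, other dose scales for the trend, fry in place of camera, the mean of a gene's probe sets, and each array left out in turn. Alternatives chosen after seeing the data were the 3' to 5' difference as a covariate, the fit without the 2 arrays of highest difference, the exact test of the lists, and each array of 132 mg/kg left out together with the covariate.

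The fit was tested on simulated data with the same group sizes and 31042 probe sets. At the size of the 1054.2 mg/kg comparison it recovered 70% of 1.5-fold, 92% of 2-fold and 100% of 3-fold changes (50 simulated at each size), and 2.69% of its calls were false. For the trend these were 94%, 96% and 100%, with 3.47% false. Camera recovered both lists that were moved and called 0 of 20 that were not, as it did with an estimated correlation and as fry did. The simulated genes varied independently of each other. The 0 therefore does not measure false calls of lists whose genes are correlated in real arrays.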

Results

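The liver transcriptome was profiled in 20 male Harlan Sprague Dawley rats after 4 daily gavage doses of IDDP in corn oil, with tissue taken on day 5. There were 5 vehicle controls and 3 rats at each of 66, 132, 263.6, 527.1 and 1054.2 mg/kg body weight, with the lowest equal to 0.169 mmol/kg and the highest to 2.7 mmol/kg. Each array was made from 100 ng of total RNA of the left lobe. Pearson's r between any pair of arrays, across probe sets, lay between 0.978 and 0.996. The 3' minus 5' difference of the beta-actin and GAPDH control probe sets, which is larger where RNA is more degraded, was 1.64 ± 0.27 log2 (SD, n = 5) in controls. It was 1.76 ± 0.25 at 66, 2.31 ± 0.89 at 132, 1.92 ± 0.48 at 263.6, 1.69 ± 0.10 at 527.1 and 1.68 ± 0.11 at 1054.2 mg/kg (SD, n = 3 each). The highest arrays were 132 mg/kg replicate 2 (3.25) and 263.6 mg/kg replicate 2 (2.47). The number of probe sets that differed from the controls was 2, 21, 133, 520 and 1024 from the lowest to the highest dose.

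**Figure D1:**
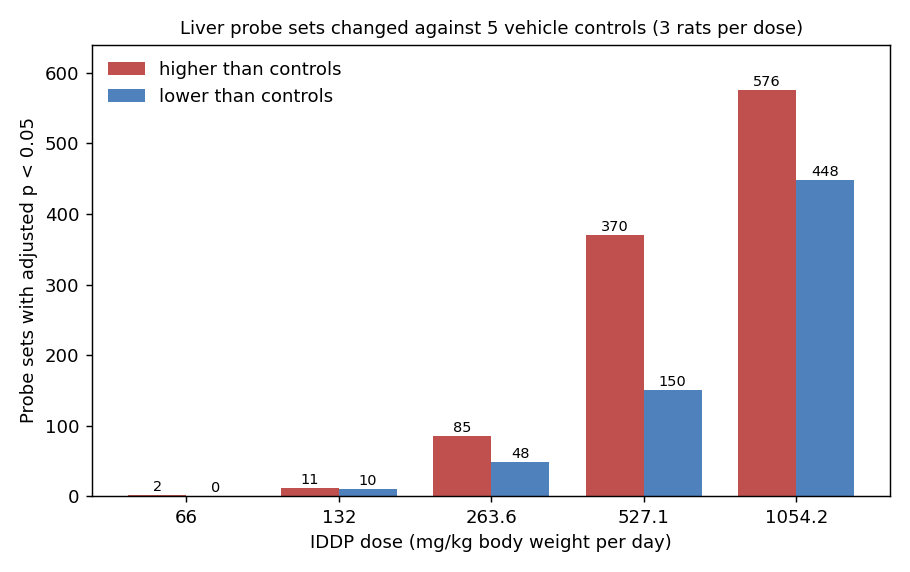
Probe sets higher or lower than in the 5 controls at each dose (vertical axis, number of probe sets with limma adjusted p under 0.05; horizontal axis, dose in mg/kg, 3 rats each). The counts rise from 2 at 66 mg/kg to 1024 at 1054.2 mg/kg, of which 576 were higher and 448 lower.

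The comparison of 1054.2 mg/kg with the controls asks which liver transcripts differ at the highest dose given. The largest rise was in Ces2c, a carboxylesterase, from a log2 level of 8.83 ± 0.07 (SD, n = 5) to 12.43 ± 0.38 (SD, n = 3), or 12.2-fold (log2 3.60 ± 0.17 SE, adjusted p = 1.65e-10). Dbp, a transcription factor driven by the circadian clock, rose by 3.44 ± 0.27 (adjusted p = 2.44e-07) from a dim control level of 5.96, and Abcc3, an efflux transporter of organic anions, rose 10.7-fold (3.42 ± 0.28, adjusted p = 4.34e-07). The glutathione transferase Gsta3 rose 7.79-fold (2.96 ± 0.17, adjusted p = 2.43e-09). The largest falls were in Scd, the desaturase that makes oleate from stearate, which was 14.8-fold lower (log2 change -3.89 ± 0.48, adjusted p = 7.64e-05), and in the taurine transporter Slc6a6, which was 14.5-fold lower (-3.86 ± 0.20, adjusted p = 4.36e-10).

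The other genes with the largest rises at 1054.2 mg/kg were Snx10 (2.38 ± 0.49), the aldo-keto reductase Akr1b7 (2.23 ± 0.24), Nfe2 (2.16 ± 0.49), the growth-related transcription factor Myc (1.94 ± 0.24), the aldehyde reductase Akr7a3 (1.91 ± 0.23), Hsd17b2, which oxidises estradiol and testosterone (1.87 ± 0.19), the clock gene Per3 (1.86 ± 0.22) and Cryl1 (1.80 ± 0.15). Those with the largest falls were Stac3 (-2.87 ± 0.52), the clock activator Npas2 (-2.65 ± 0.28), the tubulin gene Tubb2a (-2.26 ± 0.17), Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (-2.14 ± 0.24), Dhrs7l1 (-2.12 ± 0.29), the immediate early gene Egr1 (-2.10 ± 0.37), the collagen cross-linking enzyme gene Lox (-2.06 ± 0.53), the phosphate transporter Slc34a2 (-1.82 ± 0.31), the phosphatidate phosphatase Lpin1 (-1.68 ± 0.38) and Rgs16 (-1.67 ± 0.42). These are log2 changes with SE, and for every gene named from the largest changes all 3 treated rats lay on the same side of the control mean. Control levels were dim for Akr1b7 (4.70), Per3 (5.17), Snx10 (5.91) and Nfe2 (5.98). A second probe set of Per3 had a change of 0.00 and did not pass, while both probe sets of Slc6a6, Cdkn1a, Lox, Lpin1 and Snx10 passed in the same direction. The second probe sets of those genes changed less, by -2.56, -0.75, -1.88, -1.44 and 1.14 in that order. The adjusted p exceeded the threshold for Snx10 without 1054.2 mg/kg replicate 3 (0.0949), for Nfe2 without its replicates 2 or 3 (0.0920 and 0.113), and for Lpin1 without its replicates 1 or 3 (0.0617 and 0.0755). It did so for Rgs16 without control replicates 1, 3, 4 or 5 or treated replicates 2 or 3 (0.0530 to 0.160), and for Lox without control replicates 1, 2 or 5 or any 1 of the treated rats (0.0690 to 0.166).

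In all, 1024 probe sets passed limma's test at 1054.2 mg/kg, 576 higher and 448 lower, for 751 genes with 1 symbol (421 higher and 330 lower). Of the 1024, 518 changed by at least 1.5-fold. At an unadjusted p under 0.05 there were 4683, against 1552.1 by chance. The count was 647 without control replicate 4, 529 without 1054.2 mg/kg replicate 2 and 405 without its replicate 3.

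**Figure D2:**
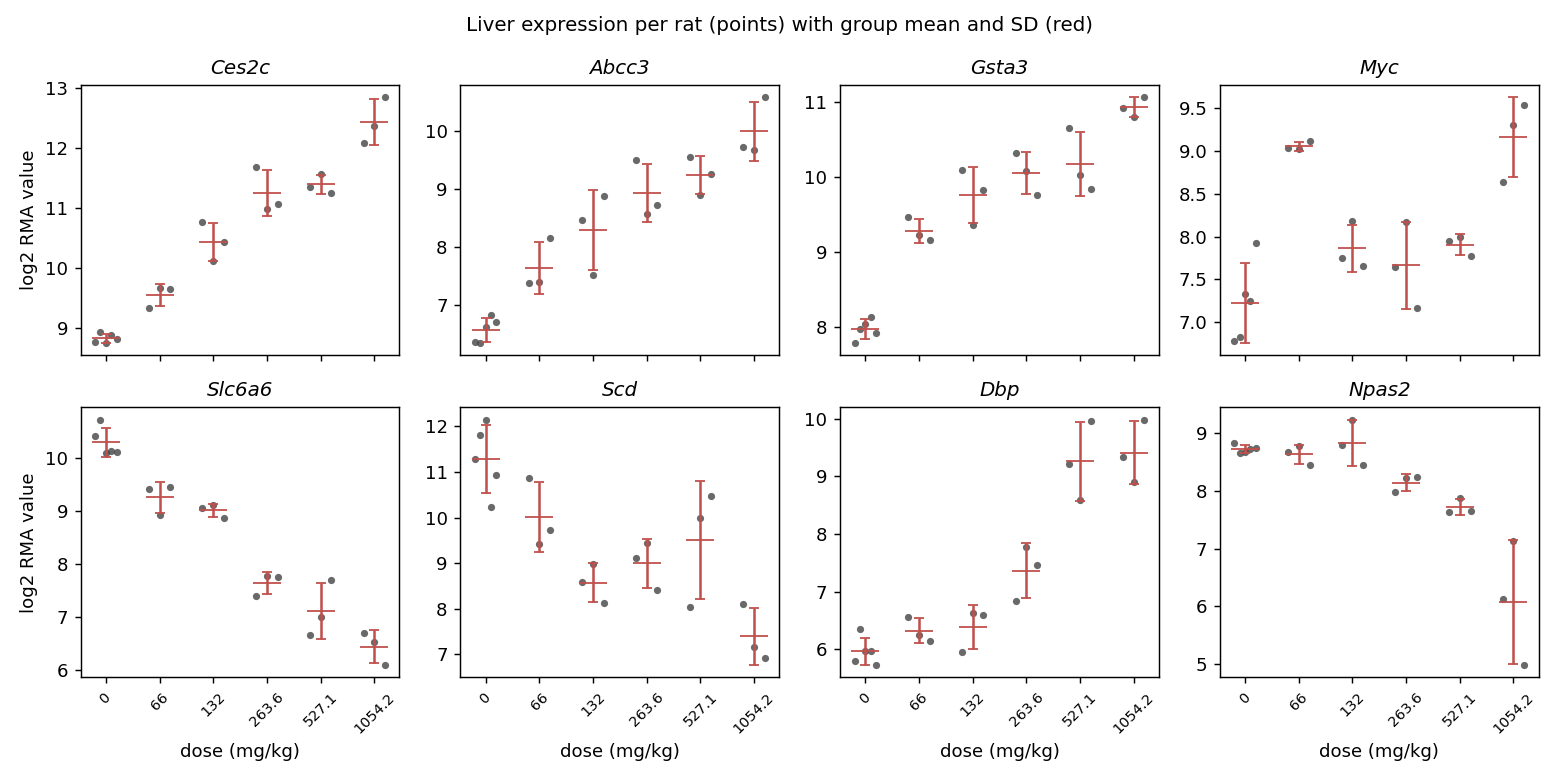
Log2 expression of 8 genes in each rat (vertical axis) at each dose of IDDP in mg/kg (horizontal axis), with black points for rats and red marks for the group mean and SD. Ces2c, Abcc3 and Gsta3 are higher and Slc6a6 lower at the higher doses, and Myc lies above the control mean in every treated rat except 263.6 mg/kg replicate 3.

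Targets of CAR and PXR, nuclear receptors that induce drug metabolism, rose together at 1054.2 mg/kg. Of 22 measured members 14 rose and 8 did not pass, or 17 rose when adjusted over the list alone. Beside Ces2c and Abcc3, Akr7a3 and the efflux pump gene Abcb1a (1.60 ± 0.13, adjusted p = 5.14e-07) were among those that rose. The mean of the list was 0.96 ± 0.13 log2 higher (SD, n = 3; camera adjusted p = 4.98e-24; exact permutation p = 0.0179), and the call held with an estimated correlation (adjusted p = 0.00196). Of 29 measured NRF2 targets, antioxidant and detoxification genes, 15 rose and 14 did not pass, or 23 rose adjusted over the list alone. They included the quinone reductase gene Nqo1 (1.62 ± 0.18), the haem oxygenase gene Hmox1 (1.30 ± 0.23) and Me1, which supplies NADPH (1.23 ± 0.20). The NRF2 list mean was 0.68 ± 0.21 higher (camera adjusted p = 2.15e-19; 0.0168 with an estimated correlation). Of 19 glutathione transferases 7 rose and 12 did not pass, or 12 rose adjusted over the list alone, among them Gsta3, Gstt3 (1.36 ± 0.21), Gsta4 (1.13 ± 0.11) and Mgst2 (0.80 ± 0.11). Their mean was 0.51 ± 0.15 higher (camera adjusted p = 2.47e-09; 0.0329 with an estimated correlation). These lists share members, 10 of the CAR and PXR list, 9 of the NRF2 list and 5 of the transferases being in another list.

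Carboxylesterases and paraoxonases went both ways: of 17 measured, Ces2c rose, the hepatic lipase gene Lipc (-0.52 ± 0.11) and Ces1d (-0.48 ± 0.11) fell, and 14 did not pass, with 5 higher and 2 lower adjusted over the list alone. The list mean was 0.31 ± 0.07 higher (camera adjusted p = 0.0217), a call that was lost with an estimated correlation (adjusted p = 0.201 with an estimated correlation). It was also lost without 1054.2 mg/kg replicate 2 (0.0998). Lipc did not pass without 1054.2 mg/kg replicate 3 (0.0977), nor Ces1d without replicates 2 or 3 (0.0720 and 0.113). Of 7 targets of AhR, the receptor for dioxin-like ligands, Nqo1 and Cyp1a1 (1.32 ± 0.27) rose, Cyp1a2 fell (-0.66 ± 0.11) and 4 did not pass, with the same 2 higher and 1 lower adjusted over the list alone. Cyp1a1, dim in controls (5.69), did not pass without 1054.2 mg/kg replicate 3 (0.0674). The AhR list did not pass (camera adjusted p = 0.740), and its mean (0.26) and median (-0.13) differ in sign.

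Most of the fatty acid synthesis genes that passed were lower at 1054.2 mg/kg, and most of the list did not pass. Of 21 fatty acid synthesis genes 4 fell, 1 rose and 16 did not pass, or 7 fell and 2 rose adjusted over the list alone. Scd, Lpin1 and the pyruvate kinase gene Pklr (-1.02 ± 0.21) fell and Me1 rose. The list mean was -0.37 ± 0.05 (camera adjusted p = 0.00897; adjusted p = 0.167 with an estimated correlation). Pklr did not pass without 1054.2 mg/kg replicates 2 or 3 (0.0657 and 0.0810). Among 44 PPARalpha targets, 3 fell, 1 rose and 40 did not pass, with 8 lower and 11 higher adjusted over the list alone, and the list did not pass (mean 0.03, camera adjusted p = 0.675). Angptl4, an inhibitor of lipoprotein lipase (-1.57 ± 0.24), the lipid droplet gene Plin2 (-1.41 ± 0.16) and Pdk4 (-0.95 ± 0.25) fell, and Decr1, of fatty acid oxidation, rose (0.49 ± 0.10). Pdk4 did not pass without control replicates 1, 2, 3 or 4 or any 1 of the treated rats (0.0577 to 0.217). Of 20 bile acid genes 3 fell and 17 did not pass, with the same 3 adjusted over the list alone: Slc27a5 (-0.69 ± 0.13), Abcb4 (-0.53 ± 0.13) and Fgfr4 (-0.41 ± 0.10). The list did not pass (mean -0.01, camera adjusted p = 0.215). Slc27a5 did not pass without 1054.2 mg/kg replicate 3 (0.0643), Abcb4 without control replicates 2 or 5 or treated replicates 2 or 3 (0.0527 to 0.204), and Fgfr4 without control replicates 2, 3, 4 or 5 or treated replicates 2 or 3 (0.0586 to 0.147).

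Cholesterol genes did not move as a list. In limma 0 of 21 passed, 4 at an unadjusted p under 0.05, and 3 were lower adjusted over the list alone, with the largest change in Pmvk (-0.48 ± 0.14, adjusted p = 0.0695). The mean of the list was 0.00 and its median 0.06, while camera gave its direction as down (adjusted p = 0.705). Gluconeogenesis genes were alike in limma, with 0 of 15 past the threshold, 4 at an unadjusted p under 0.05, and 1 higher and 2 lower adjusted over the list alone. Their mean was -0.05 (camera adjusted p = 0.664), and the largest change was in the serine dehydratase gene Sds (-0.68 ± 0.24, adjusted p = 0.138).

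Genes of the circadian clock moved in both directions at 1054.2 mg/kg. Of 17 measured, 7 rose, 3 fell and 7 did not pass, with the same numbers adjusted over the list alone. Per2 is among those that did not pass by the probe set used (0.03), while its other probe set was higher (1.69 ± 0.32, adjusted p = 0.00411; 0.0539 without 1054.2 mg/kg replicate 3), a value noted after it was seen. Dbp, Per3, Nr1d1 (1.66 ± 0.24), Nr1d2 (1.62 ± 0.18), Tef (0.94 ± 0.12), Cry2 (0.84 ± 0.12) and Bhlhe41 (0.46 ± 0.12) rose. Npas2, Bmal1 (-1.58 ± 0.19) and Nfil3 (-0.86 ± 0.20) fell; Bmal1 and Npas2 encode activators of the clock and Nr1d1 a repressor of Bmal1. The list mean was 0.37 ± 0.06 higher (camera adjusted p = 0.00492; 0.0329 with an estimated correlation; exact permutation p = 0.0179).

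Cell cycle genes were higher on average, with a wide spread between rats. Of 41 measured, 3 rose and 38 did not pass, or 12 rose adjusted over the list alone: Kif11 (0.70 ± 0.18), Mcm4 (0.59 ± 0.14) and Bub1b (0.47 ± 0.11). The mean per rat ran from 0.00 to 0.72 around 0.45 ± 0.39 (SD, n = 3), against -0.11 to 0.26 in controls (exact permutation p = 0.0536; camera adjusted p = 3.00e-09; adjusted p = 0.214 with an estimated correlation). Mcm4 did not pass without 1054.2 mg/kg replicates 2 or 3 (0.153 and 0.0624), nor did Bub1b without these or control replicate 3 (0.0510 to 0.132). Kif11 did not pass without these or without control replicates 1, 2, 3 or 4 (0.0506 to 0.242), and its second probe set had a change of 0.03. Kif11 and Bub1b were dim in controls (5.69 and 5.12). Among 15 p53 targets Cdkn1a and Phlda3 (-0.87 ± 0.19) fell, Mdm2 (0.65 ± 0.10) and Fas (0.59 ± 0.14) rose and 11 did not pass, or 6 rose and 3 fell adjusted over the list alone. The p53 list did not pass (mean -0.03, median 0.10, camera direction up, adjusted p = 0.499). Phlda3 did not pass without 1054.2 mg/kg replicate 2 (0.0627), nor Fas without replicates 2 or 3 (0.0920 and 0.0632). Of 3 probe sets each, 1 of Mdm2 and 2 of Fas did not pass.

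Of 28 measured members of the unfolded protein and ATF4 list 6 rose at 1054.2 mg/kg and 22 did not pass, or 8 rose adjusted over the list alone. Psat1 (1.70 ± 0.37), which acts in serine synthesis, Asns (1.69 ± 0.40), the asparagine synthetase gene, Phgdh (1.27 ± 0.30) and Trib3 (1.15 ± 0.30) had the largest rises. Without 1054.2 mg/kg replicate 3 none of these 4 passed (0.0906, 0.150, 0.143 and 0.230), and Trib3 also did not pass without control replicates 1, 2, 4 or 5 or treated replicates 1 or 2 (0.0551 to 0.0960). The list did not pass (mean 0.25, camera adjusted p = 0.188).

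Sex-biased and zonal hepatocyte genes changed in part. Of 12 male-predominant genes Akr1b7 and Cyp3a18 (1.06 ± 0.14) rose, Stac3 and Cyp2c11, a testosterone hydroxylase (-0.83 ± 0.10), fell and 8 did not pass, or 3 rose and 3 fell adjusted over the list alone (mean -0.13, camera adjusted p = 0.670). Of 7 female-predominant genes Cux2 rose (0.90 ± 0.20), and was also the 1 that rose adjusted over the list alone (mean 0.19, camera adjusted p = 0.413). Akr1b7 and Cux2 were dim in these male controls (4.70 and 5.22), and Cux2 did not pass without 1054.2 mg/kg replicate 1 (0.0849). Of 15 pericentral genes 3 fell, 1 rose and 11 did not pass, or 6 fell and 1 rose adjusted over the list alone. Oat (-1.46 ± 0.28), Gulo (-0.81 ± 0.11) and Cyp1a2 fell and Aldh1a1 rose (1.36 ± 0.10). The pericentral mean was -0.21 ± 0.04 (camera adjusted p = 0.0153; adjusted p = 0.222 with an estimated correlation). Of 18 periportal genes Sfxn1 rose (0.38 ± 0.09) and 17 did not pass, or 3 rose and 4 fell adjusted over the list alone (mean -0.09, camera adjusted p = 0.499). Sfxn1 did not pass without control replicate 1 or treated replicates 2 or 3 (0.0527 to 0.150).

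Some markers of several other liver cell types were lower at 1054.2 mg/kg, while most markers of each list did not pass. Of 14 Kupffer cell and macrophage markers 6 fell and 8 did not pass, or 12 fell and 1 rose adjusted over the list alone, with C1qb (-0.74 ± 0.18), Cd5l (-0.65 ± 0.14), Clec4f (-0.54 ± 0.12) and Csf1r (-0.54 ± 0.13) the largest. Their mean was -0.44 ± 0.06 (camera adjusted p = 1.02e-08; adjusted p = 0.119 with an estimated correlation; exact permutation p = 0.0179). Of 17 stellate cell and fibroblast markers 6 fell and 11 did not pass, or 7 fell adjusted over the list alone, with Lrat, which stores retinol as esters (-0.86 ± 0.21), Pdgfrb (-0.77 ± 0.15), Col3a1 (-0.76 ± 0.17) and Ecm1 (-0.68 ± 0.18) the largest. Their mean was -0.36 ± 0.08 (camera adjusted p = 3.02e-05; adjusted p = 0.156 with an estimated correlation; exact permutation p = 0.0179). Of 14 endothelial markers Gpr182 (-0.53 ± 0.12) and Pecam1 (-0.51 ± 0.12) fell and 12 did not pass, or 4 fell adjusted over the list alone (mean -0.32 ± 0.19; camera adjusted p = 3.94e-05; adjusted p = 0.201 with an estimated correlation). The endothelial mean of 1054.2 mg/kg replicate 1 (-0.10) lay within the range of the controls, whose replicate 5 was at -0.17. Without 1054.2 mg/kg replicate 3, Cd5l (0.0643), Clec4f (0.111), Pdgfrb (0.0682), Col3a1 (0.0552) and Gpr182 (0.115) did not pass. Without its replicate 2, Col3a1 (0.0616), Gpr182 (0.0571) and Pecam1 (0.0904) did not pass. C1qb and Csf1r passed only with control replicates 1 and 4 and all treated rats (0.0516 to 0.113 without 1 of them), Lrat only with control replicates 1, 2, 3 and 4 and all treated rats (0.0565 to 0.106), and Ecm1 only with all 8 rats (0.0521 to 0.232). Other probe sets of Pdgfrb did not pass, the highest at 0.02. The 3' minus 5' difference was 1.68 ± 0.11 at this dose and 1.64 ± 0.27 in controls.

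Of 12 cholangiocyte markers Epcam rose at 1054.2 mg/kg (0.65 ± 0.12) and 11 did not pass, with the same 1 adjusted over the list alone (mean 0.12, camera adjusted p = 0.188). Of 12 pancreas markers Cela1 fell (-0.80 ± 0.15), with the same 1 adjusted over the list alone (mean -0.13, camera adjusted p = 0.0733). Of 28 acute phase and inflammation genes Orm1 rose (0.69 ± 0.19), with the same 1 adjusted over the list alone (mean -0.06, camera adjusted p = 0.705). Orm1 did not pass without control replicates 1, 2 or 3 or any 1 of the treated rats (0.0688 to 0.175). In limma 0 of 8 erythroid markers passed (3 at an unadjusted p under 0.05, and 3 lower adjusted over the list alone), with the largest change in Alas2 (-0.91 ± 0.26, adjusted p = 0.0635) and a mean of -0.37 ± 0.25 (camera adjusted p = 9.76e-04; adjusted p = 0.166 with an estimated correlation). In limma 0 of 16 T and NK cell markers passed (1 at an unadjusted p under 0.05, and 0 adjusted over the list alone), with the largest change in Gzma (-0.32 ± 0.18, adjusted p = 0.438) and a mean of -0.14 ± 0.10 (camera adjusted p = 0.0217; adjusted p = 0.330 with an estimated correlation). That call was lost without control replicates 1 or 2 (0.0610 and 0.0698) and without treated replicates 2 or 3 (0.0883 and 0.0975). Limma also passed 0 of 8 neutrophil markers (1 at an unadjusted p under 0.05, 0 adjusted over the list alone; largest change S100a8, -0.40 ± 0.33, adjusted p = 0.644; camera adjusted p = 0.499) and 0 of 8 B cell markers (2 at an unadjusted p under 0.05, 1 lower adjusted over the list alone; largest change Fcrla, 0.42 ± 0.38, adjusted p = 0.691; camera adjusted p = 0.238).

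Over the 28 lists, camera called 13 at 1054.2 mg/kg, 6 higher and 7 lower, of which the CAR and PXR, NRF2, glutathione transferase and circadian clock lists held with an estimated correlation. At 66, 132, 263.6 and 527.1 mg/kg it called 11, 14, 11 and 10, of which 0, 0, 1 and 1 held, the 1 being the CAR and PXR list. The exact permutation p of the list mean was under 0.05 for 3, 9, 13, 8 and 12 lists from the lowest dose up, and 0 passed after adjustment. The number of splits sets a smallest possible p. At 66, 132 and 527.1 mg/kg too few lists were under 0.05 for any to pass after adjustment over 28 lists. At 263.6 and 1054.2 mg/kg a pass needed most of those lists to have the smallest p. The 0 therefore does not count against the lists.

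**Figure D3:**
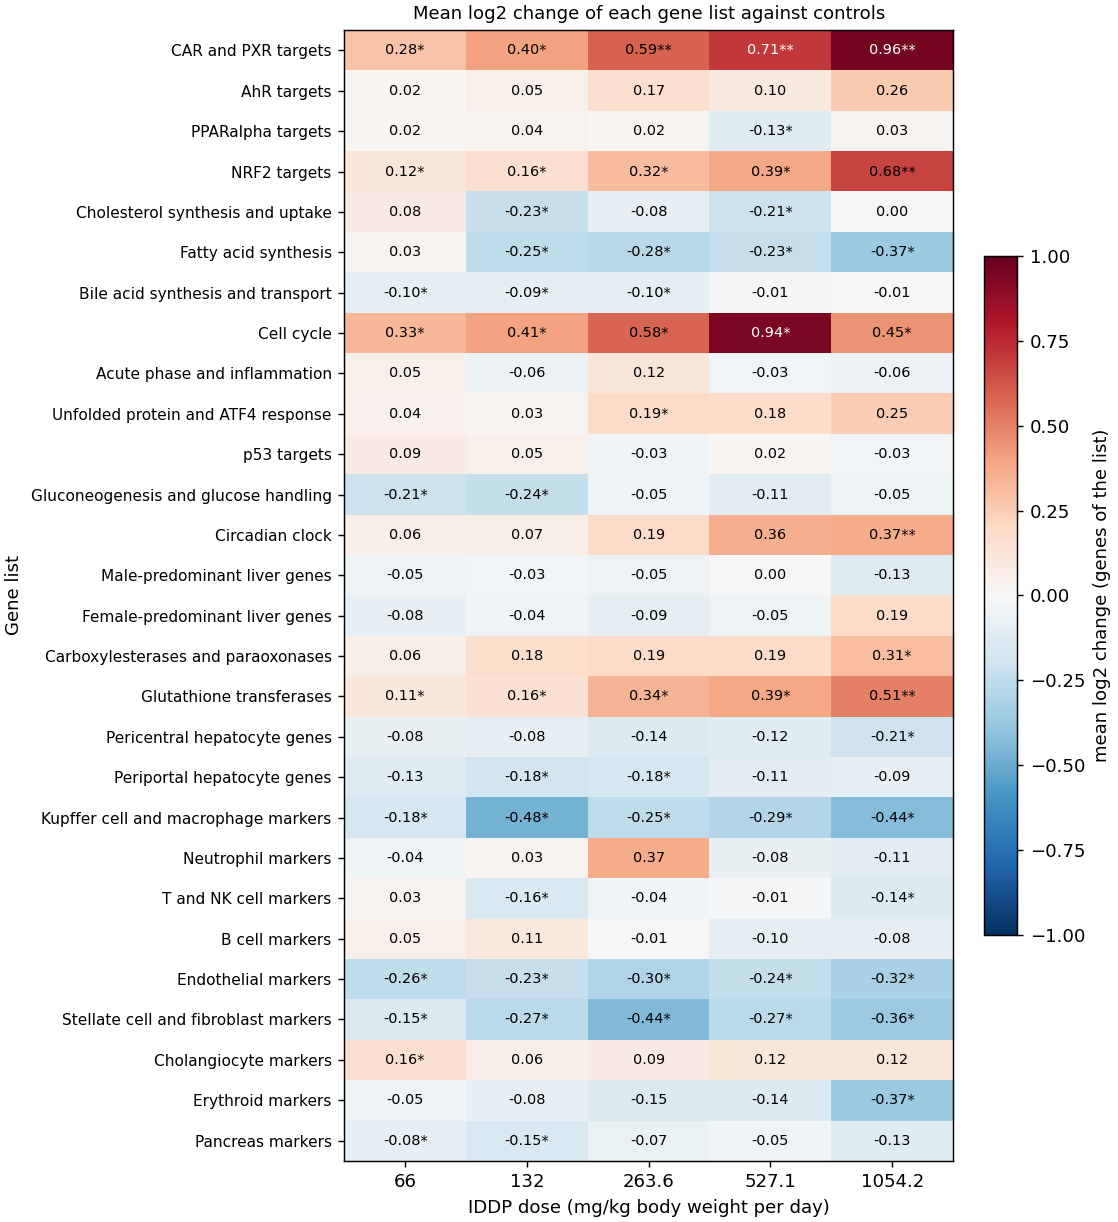
Mean log2 change of the measured genes of each of the 28 lists (vertical axis) against the controls at each dose in mg/kg (horizontal axis), with red for higher and blue for lower. One star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation; the CAR and PXR mean runs from 0.28 at 66 to 0.96 at 1054.2 mg/kg, and the cell cycle mean is 0.94 at 527.1 mg/kg.

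At 527.1 mg/kg Cdkn3, a phosphatase gene of the cell cycle, rose 5.97-fold (log2 2.58 ± 0.39, SE, n = 3 against 5, adjusted p = 0.00158). Dbp rose by 3.29 ± 0.27, Abcc3 6.31-fold (2.66 ± 0.28), Ces2c 5.90-fold (2.56 ± 0.17) and Nr1d1 4.88-fold (2.29 ± 0.24). Slc6a6 was 9.03-fold lower (-3.18 ± 0.20, adjusted p = 3.28e-08), Egr1 4.37-fold (-2.13 ± 0.37), Lpin1 3.59-fold (-1.84 ± 0.38), Tubb2a 3.15-fold (-1.66 ± 0.17) and Cdkn1a 2.64-fold (-1.40 ± 0.24).

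Of the 41 cell cycle genes 24 rose at 527.1 mg/kg and 17 did not pass, or 30 rose adjusted over the list alone, among them Ect2 (2.16 ± 0.40), the proliferation marker Mki67 (2.13 ± 0.35) and the cyclin gene Ccnb2 (2.02 ± 0.30), members named after their values were seen. Ect2 did not pass without 527.1 mg/kg replicate 1 (0.0609). The list mean was 0.94 ± 0.20 (SD, n = 3), with all 3 rats (0.73 to 1.14) above the highest control (0.26; exact permutation p = 0.0179). Camera's adjusted p was 4.17e-27, and the call was lost with an estimated correlation (adjusted p = 0.0729 with an estimated correlation). Of the CAR and PXR targets 10 rose, or 14 adjusted over the list alone (mean 0.71, camera adjusted p = 8.33e-18; 0.00888 with an estimated correlation). Of the NRF2 targets 7 rose, or 10 adjusted over the list alone (mean 0.39, camera adjusted p = 3.38e-09; adjusted p = 0.123 with an estimated correlation), and of the glutathione transferases 5 rose, or 8 adjusted over the list alone (mean 0.39, camera adjusted p = 2.83e-06; adjusted p = 0.123 with an estimated correlation). Of the clock genes 6 rose and 2 fell, or 6 and 4 adjusted over the list alone, although the list missed the threshold in camera (mean 0.36, adjusted p = 0.0529). Of the PPARalpha targets 4 fell, or 8 adjusted over the list alone (mean -0.13, camera adjusted p = 0.00235; adjusted p = 0.479 with an estimated correlation), with Plin2 (-0.93 ± 0.16, named after its values were seen) passing also without each array in turn. Pdk4, Angptl4 and Cpt1b, which also fell and were named after their values were seen, were less stable. Pdk4 did not pass without 527.1 mg/kg replicates 1 or 3 (0.102 and 0.0787), nor Angptl4 without replicates 1 or 2 (0.0768 and 0.0548). Cpt1b did not pass without control replicates 1, 3 or 4 or any 1 of the treated rats (0.0806 to 0.131). The PPARalpha list did not pass without 527.1 mg/kg replicate 1 (0.0537). The means of the Kupffer (-0.29), endothelial (-0.24) and stellate (-0.27) marker lists were lower in camera (adjusted p = 1.61e-05, 6.84e-04 and 0.00150), calls that were lost with an estimated correlation (adjusted p = 0.294, 0.357 and 0.294 with an estimated correlation). The 3' minus 5' difference was 1.69 ± 0.10, within the range of the controls.

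Limma passed 520 probe sets at 527.1 mg/kg, 370 higher and 150 lower, for 401 genes (296 higher and 105 lower), and 4215 at an unadjusted p under 0.05. The count was 285 and 302 without control replicates 3 and 4, and 215, 299 and 212 without 527.1 mg/kg replicates 1, 2 and 3. Lpin1 did not pass without 527.1 mg/kg replicates 1 or 3 (0.116 and 0.0603).

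At 263.6 mg/kg Ces2c rose 5.33-fold (2.42 ± 0.17, SE, n = 3 against 5, adjusted p = 2.75e-07), Abcc3 5.12-fold (2.36 ± 0.28), Gsta3 4.25-fold (2.09 ± 0.17), Nr1d1 3.45-fold (1.79 ± 0.24) and Mki67, dim in controls (5.15), by 1.73 ± 0.35 (adjusted p = 0.0339). Slc6a6 was 6.28-fold lower (-2.65 ± 0.20, adjusted p = 4.30e-07). Scd (-2.29 ± 0.48, adjusted p = 0.0387), Ppp1r3b, which targets a phosphatase to glycogen (-1.34 ± 0.21), the ornithine aminotransferase gene Oat (-1.33 ± 0.28, adjusted p = 0.0376) and Tubb2a (-1.17 ± 0.17) also fell. Scd did not pass without control replicates 1, 2 or 3 or any 1 of the treated rats (0.0840 to 0.109), Oat without control replicates 1 to 4 or any treated rat (0.0608 to 0.168), and Mki67 without control replicates 1 to 4 or treated replicates 2 or 3 (0.0705 to 0.165).

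Of the CAR and PXR targets 7 rose at 263.6 mg/kg, or 12 adjusted over the list alone (mean 0.59 ± 0.07, camera adjusted p = 5.02e-14; 0.0253 with an estimated correlation). Of the glutathione transferases 5 rose, or 7 adjusted over the list alone (mean 0.34, camera adjusted p = 9.52e-06; adjusted p = 0.175 with an estimated correlation), and of the NRF2 targets 3 rose, or 8 adjusted over the list alone (mean 0.32, camera adjusted p = 6.23e-05; adjusted p = 0.263 with an estimated correlation). Of the cell cycle genes 6 rose, or 24 with 1 fall adjusted over the list alone. Their mean was 0.58 ± 0.40, from 0.13 to 0.91 per rat (camera adjusted p = 2.50e-14; adjusted p = 0.175 with an estimated correlation). Of the clock genes 4 rose, or 6 with 1 fall adjusted over the list alone (mean 0.19, camera adjusted p = 0.172). Stellate cell markers had a mean of -0.44 ± 0.19 (camera adjusted p = 1.46e-07; adjusted p = 0.145 with an estimated correlation), with 0 of 17 past limma's test, 11 at an unadjusted p under 0.05 and 8 lower adjusted over the list alone. Endothelial markers had a mean of -0.30 ± 0.03 (camera adjusted p = 4.09e-06; adjusted p = 0.205 with an estimated correlation). The neutrophil marker S100a9, named after its values were seen, rose (1.46 ± 0.30, adjusted p = 0.0339), and the neutrophil list did not pass (mean 0.37 ± 0.21, camera adjusted p = 0.0607). S100a9 did not pass without control replicates 1, 2, 3 or 4 or 263.6 mg/kg replicates 1 or 2 (0.0538 to 0.166). The 3' minus 5' difference at this dose was 1.92 ± 0.48, with 2.47 in replicate 2.

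Limma passed 133 probe sets at 263.6 mg/kg, 85 higher and 48 lower, for 102 genes, and 3689 at an unadjusted p under 0.05. The count was 48, 59, 46 and 58 without control replicates 1, 2, 3 and 4, and 78 and 38 without 263.6 mg/kg replicates 1 and 2. Without the 2 arrays of highest 3' minus 5' difference, a choice made after seeing the data, it was 56.

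At 132 mg/kg Gsta3 rose 3.47-fold (1.80 ± 0.17, SE, n = 3 against 5, adjusted p = 5.45e-05), Abcc3 3.29-fold (1.72 ± 0.28), Ces2c 3.04-fold (1.60 ± 0.17), Cryl1 2.02-fold (1.02 ± 0.15) and the glucuronosyltransferase gene Ugt2b1 1.87-fold (0.90 ± 0.10, adjusted p = 3.09e-04). Scd was 6.57-fold lower (-2.72 ± 0.48, adjusted p = 0.0313), Insig1, a regulator of sterol synthesis, 3.16-fold (-1.66 ± 0.29), Sds 2.55-fold (-1.35 ± 0.24) and Slc6a6 2.43-fold (-1.28 ± 0.20), and Aacs, which activates acetoacetate, fell to a dim level of 6.25 (-1.08 ± 0.19). Of the CAR and PXR targets 5 rose, or 9 adjusted over the list alone (mean 0.40 ± 0.15, camera adjusted p = 2.48e-07; adjusted p = 0.134 with an estimated correlation). Kupffer cell markers had a mean of -0.48 ± 0.10 (camera adjusted p = 1.90e-12; adjusted p = 0.134 with an estimated correlation), with 0 of 14 past limma's test, 10 at an unadjusted p under 0.05 and 10 lower adjusted over the list alone. Cell cycle genes had a mean of 0.41 ± 0.12 (camera adjusted p = 3.97e-06; adjusted p = 0.361 with an estimated correlation), with 0 of 41 past limma's test, 19 at an unadjusted p under 0.05 and 10 higher adjusted over the list alone. The cholesterol list, which holds Insig1, had a mean of -0.23 (camera adjusted p = 0.0106; adjusted p = 0.484 with an estimated correlation) and did not pass without control replicate 5 or 132 mg/kg replicate 2 (0.0680 and 0.185). The 3' minus 5' difference was 2.31 ± 0.89 at this dose, the highest mean of the 6 groups.

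Without single rats the changes at 132 mg/kg kept their direction, and the adjusted p of several exceeded 0.05. Scd (-2.50 to -2.92; adjusted p 0.0761 to 0.0962) did not pass without control replicates 1, 2 or 3 or 132 mg/kg replicates 1 or 2, Insig1 (-1.50 to -1.68; 0.0566 to 0.154) without control replicates 1, 3 or 4 or treated replicates 1 or 2, Sds (-1.14 to -1.39; 0.0654 to 0.239) without control replicates 1 or 4 or treated replicates 1 or 2, and Aacs (-0.997 to -1.18; 0.0538 to 0.181) without control replicates 1, 2 or 3 or treated replicates 1 or 2. Slc6a6 (-1.31 and -1.33) did not pass without 132 mg/kg replicates 1 or 2 (0.0671 and 0.0515), nor Cryl1 without replicate 1 (0.0692), nor Abcc3 without replicate 1 or control replicate 1 (0.0752 and 0.0561). Limma passed 21 probe sets, 11 higher and 10 lower, for 16 genes, and 4623 at an unadjusted p under 0.05. The split was 18 higher and 8 lower with array medians centred, and 24 higher and 26 lower with quantile normalization applied again. The count was 9 without control replicate 1, 6 without 132 mg/kg replicate 1, 9 without replicate 2 and 1482 without replicate 3, whose 3' minus 5' difference of 1.49 was the lowest of the 3. Without replicate 3 but with that difference as a covariate it was 4, an alternative added after the count of 1482 was seen.

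At 66 mg/kg Myc rose 3.57-fold, from 7.22 ± 0.46 (SD, n = 5) to 9.06 ± 0.05 (SD, n = 3; log2 change 1.83 ± 0.24 SE, adjusted p = 0.00418), and Gsta3 rose 2.48-fold (1.31 ± 0.17, adjusted p = 0.00418). These were the only 2 probe sets past limma's threshold, and 1005 had an unadjusted p under 0.05, against 1552.1 by chance. Neither passed without 66 mg/kg replicate 1, where the count was 0 and the adjusted p 0.0995 for Myc and 0.110 for Gsta3. Of the CAR and PXR targets 0 of 22 passed limma's test, 10 at an unadjusted p under 0.05 and 8, all higher, adjusted over the list alone. The list mean was 0.28 ± 0.05 and each of the 3 rats (0.23 to 0.31) lay above the highest control (0.10; exact permutation p = 0.0179). Camera called the list (adjusted p = 3.41e-11), and the call was lost with an estimated correlation (adjusted p = 0.0625 with an estimated correlation).

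The contrast of the highest doses with each other tests whether effects went on growing between 527.1 and 1054.2 mg/kg. Akr1b7 was higher at 1054.2 mg/kg (6.94 ± 0.64 against 4.84 ± 0.39, SD; log2 difference 2.09 ± 0.27 SE, n = 3 against 3, adjusted p = 0.00586), as was Srxn1, which repairs oxidised peroxiredoxins (6.43 ± 0.05 against 5.78 ± 0.19; 0.65 ± 0.10, adjusted p = 0.0196). Both lie under the dim threshold of 6.37 at 527.1 mg/kg, so no fold is given, and the other 2 probe sets of Srxn1 did not pass in this contrast. Dhrs7l1 was 4.76-fold lower (-2.25 ± 0.33, adjusted p = 0.0196). The remaining call, a probe set with the symbol LOC102555217, falls outside the naming rule and was chosen after its values were seen (1.04 ± 0.16, adjusted p = 0.0196). These were all 4 that passed in limma, with 1888 at an unadjusted p under 0.05. None of them, Akr1b7 included (0.183, the highest adjusted p over its alternatives), passed when only these groups were fitted. The count was 1 without 527.1 mg/kg replicate 1, and 8, 7 and 2 without 1054.2 mg/kg replicates 1, 2 and 3. Srxn1 did not pass without 527.1 mg/kg replicates 1 or 2 or 1054.2 mg/kg replicates 2 or 3 (0.0727 to 0.104), nor Dhrs7l1 without replicates 1 or 3 of either dose (0.0525 to 0.104). The mean of the cell cycle list differed by -0.49 between 1054.2 and 527.1 mg/kg, with an exact permutation p of 0.1, the smallest that 3 rats against 3 allow. Camera's adjusted p for it was 8.02e-12, and 0.331 with an estimated correlation.

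Between 1054.2 and 66 mg/kg, Dbp (3.08 ± 0.30, SE, n = 3 against 3), Ces2c (2.88 ± 0.19, adjusted p = 8.62e-08), Nfe2 (2.77 ± 0.55), Akr1b7 (2.42 ± 0.27) and Abcc3 (2.35 ± 0.31) were higher at the higher dose. Slc6a6 (-2.83 ± 0.22, adjusted p = 1.01e-06), Scd (-2.61 ± 0.54), Npas2 (-2.55 ± 0.31), Cdkn1a (-2.20 ± 0.27) and Egr1 (-2.14 ± 0.42) were lower. Limma passed 154 probe sets, 96 higher and 58 lower, for 116 genes, and 2274 at an unadjusted p under 0.05. The count was 86, 87 and 62 without 66 mg/kg replicates 1, 2 and 3, and 90 and 42 without 1054.2 mg/kg replicates 2 and 3. Nfe2 did not pass without replicates 2 or 3 of either dose (0.0974 to 0.156), nor Egr1 (0.0745 to 0.127), nor Scd without 66 mg/kg replicates 1 or 3 or 1054.2 mg/kg replicates 2 or 3 (0.0890 to 0.187). Npas2 did not pass under 1 of its 15 alternatives (limma adjusted p = 0.0519).

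Across all 20 rats Ces2c rose by 0.70 ± 0.03 log2 (SE) per dose step (adjusted p = 3.04e-12), followed by Abcc3 (0.66 ± 0.05), Gsta3 (0.54 ± 0.04), Cryl1 (0.35 ± 0.03) and the retinal dehydrogenase gene Aldh1a1 (0.26 ± 0.02). Slc6a6 fell by 0.78 per step (SE 0.04, adjusted p = 3.49e-12), followed by Tubb2a (-0.45 ± 0.03), the vasopressin receptor gene Avpr1a (-0.30 ± 0.03), Plin2 (-0.27 ± 0.03) and the lactate transporter gene Slc16a1 (-0.20 ± 0.02). These were the genes of smallest p in each direction. The trend was past the threshold in 1569 probe sets, 922 rising and 647 falling, for 1180 genes, and 5188 had an unadjusted p under 0.05.

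Many probe sets called at lower doses were called at 1054.2 mg/kg too. Of the 2, 21, 133 and 520 called at 66, 132, 263.6 and 527.1 mg/kg, 2, 14, 85 and 268 were called at 1054.2 mg/kg, all in the same direction and 0 in the opposite one. Both sides share the 5 control rats. Independent calls would give 0.0371, 0.204, 1.58 and 6.87 shared rises and 0, 0.144, 0.693 and 2.16 shared falls, and simulated groups with no effect gave a mean of 0. Those simulations hold no effect at 1054.2 mg/kg either, so their 0 does not measure how far the shared controls raise the overlap. With the controls split between the doses over 20 ordered splits, means of 1.1, 8.45, 40.05 and 184.55 probe sets were called at the lower dose, and 1.1, 5.6, 23.75 and 74.35 of them were also called in the same direction at 1054.2 mg/kg, where the mean count was 440.85. At most 1 was called in the opposite direction in any split. Across all tested probe sets, which are not independent replicates, Pearson's r between the changes at 1054.2 mg/kg and those at 66, 132, 263.6 and 527.1 mg/kg was 0.328, 0.383, 0.391 and 0.525 with split controls. It was 0.563, 0.529, 0.550 and 0.689 with the same 5 controls on both sides, against 0.372 in simulated groups with no effect and shared controls. The covariances with split controls were 0.0124, 0.0215, 0.0207 and 0.0295, and with shared controls 0.0178, 0.0268, 0.0260 and 0.0348, against 0.00698 in the simulations. Probe sets varied independently in these simulations. They therefore do not measure how far r or the covariance spreads by chance where genes are correlated.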

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

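In this part, the tests of a later time of day and of a larger hepatocyte share were chosen only after the result was seen.

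Among the 5 control rats, 9 of 121 values (named genes and list scores) had a lowest or highest rat whose gap to the nearest other rat was over 0.71 of the whole range. Chance gives about 1 in 20, or 5%. Control replicate 2 had Nr1d1 at 7.72 (the others 6.39 to 6.67), Hsd17b2 at 10.86 (10.34 to 10.45), a cholesterol score of -0.36 (0.03 to 0.16) and a B cell score of -0.11 (0.01 to 0.05). Replicate 3 had Epcam at 8.96 (9.26 to 9.32). Replicate 4 had Gsta4 at 11.53 (11.39 to 11.43) and a gluconeogenesis score of 0.11 (-0.05 to -0.01). Replicate 5 had Angptl4 at 10.87 (11.48 to 11.62) and a stellate cell score of -0.26 (0.04 to 0.08). The replicate numbers have no order, and no further explanation of these single values was tested.

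The first pattern is the opposite movement of clock genes at 1054.2 mg/kg. In the fit with the 3' to 5' difference as a covariate, 10 of the 10 called clock genes stayed past the threshold. That fit cannot decide on RNA integrity, because the difference was nearly equal in the groups compared. It was 1.68 ± 0.11 at 1054.2 mg/kg and 1.64 ± 0.27 in controls (SD). The near equality itself argues against RNA integrity as the cause, by this measure alone. A later time of day at necropsy for the higher doses was tested by the side on which each gene lies later in the light phase: of the called genes with a side written down, 9 of 9 lay on it and 0 on the other. That explanation cannot be told apart from an effect of the dose on the clock, because a later time at the higher doses would be confounded with the dose and necropsy times are not used here. Both stay open.

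The second pattern is the lower mean of the Kupffer cell, endothelial and stellate cell marker lists, whose camera calls were lost with an estimated correlation. With the 3' to 5' difference as a covariate their mean change at 1054.2 mg/kg was -0.370 log2, against -0.373 without it. This fit could hardly move the mean, because the difference was nearly equal at that dose and in controls (1.68 ± 0.11 and 1.64 ± 0.27, SD). That near equality argues against RNA integrity, by this measure alone. A larger hepatocyte share of the RNA would lower the markers of every other cell type alike. The cholangiocyte score moved 0.498 log2 above the mean of the 3 lists (exact permutation p = 0.0179). Over markers at or above the median brightness, 6 of them cholangiocyte markers, it lay 0.627 above (0.0179). The 3 lists were picked because they fell, which favours such a gap, and these p-values do not allow for that choice. The cholangiocyte scores of 1054.2 mg/kg replicates 2 and 3 (-0.07 and 0.08) lay within the range of the controls (-0.09 to 0.15), and that of replicate 1 (0.36) above it. The gap argues only weakly against a larger share as the whole cause. Over bright markers, those of T and NK cells (5 markers, -0.17) lay 0.24 above the 3 lists (0.0357), while erythroid (3 markers, -0.63) did not lie above them. B cell (3 markers), neutrophil (1 marker) and pancreas (1 marker) markers changed by -0.12, -0.30 and -0.80. Their differences from the 3 lists were 0.29, 0.10 and -0.40 (exact permutation p = 0.0536, 0.571 and 0.0536), not clearly apart. Without Krt8 and Epcam the bright cholangiocyte markers changed by 0.11 ± 0.40 (SD) and lay 0.52 above the 3 lists (0.0357). A larger hepatocyte share together with more cholangiocyte RNA stays open, and so does an effect of the dose on the number of these cells or on their expression, which may contribute; cell counts were not analysed here.

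The third pattern is the higher level of cell cycle genes, largest on average at 527.1 mg/kg. The mean of the list at that dose was 0.948 log2 with the 3' to 5' difference as a covariate, against 0.943 without it. This fit could hardly move the mean, because the difference was nearly equal at that dose and in controls (1.69 ± 0.10 and 1.64 ± 0.27, SD). That near equality argues against RNA integrity, by this measure alone. Without any 1 of the 3 arrays the mean was at least 0.846, and the lowest array (0.73) lay above the highest control (0.26), which argues against a single rat. Over the 26 members at or above the median brightness the mean was 0.959. This brightness is a mean over all arrays, treated ones included, so a rise with dose itself helps a member past the cut. The value therefore cannot decide on signal near the background, which stays open. An effect of the dose on cell division may explain the pattern, as a hypothesis that came from these data and was not tested.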

How the results depend on the processing

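Chosen only after the result was seen were the fits with the 3' to 5' difference as a covariate, the fit without the 2 arrays of highest difference, the covariate with an array of 132 mg/kg left out, and the exact test of lists. No call reversed under any alternative that was run. Among values that had not passed, signs changed for several lists and for Fcrla at 1054.2 mg/kg (0.42, and -0.05 with array weights or without 1054.2 mg/kg replicate 2). Of 2385 values of named genes under alternatives, 2136 kept their side of the threshold, 238 no longer passed, 11 newly passed and 0 reversed; 74 of the 129 called kept every call. Of 2210 values of lists, 1957 kept their side, 188 no longer passed, 65 newly passed and 0 reversed; 5 of 59 called kept every call. Where no cause is named below, the cause was not tested.

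With single arrays left out, counts ran from 0 to 3 at 66, 6 to 1482 at 132, 38 to 193 at 263.6, 212 to 509 at 527.1 and 405 to 1069 at 1054.2 mg/kg, from 1 to 8 between 1054.2 and 527.1, from 42 to 218 between 1054.2 and 66 mg/kg and from 1092 to 1919 for the trend. List counts ran from 7 to 13, 11 to 15, 10 to 14, 9 to 12 and 12 to 14; the 7 at 66 mg/kg is without its replicate 3. With array weights the counts were 12, 37, 885, 1188 and 6439 from the lowest dose up, 656 and 2311 for the contrasts between doses and 2681 for the trend. With the replicate number as a block they were 78 at 263.6, 283 at 527.1, 614 at 1054.2, 1 between the highest doses and 930 for the trend. Each array is a different rat, and the labels give no shared animal behind a number, so the pairing was not used. Over 45 pairs with the same number the residuals had r from -0.352 to 0.472 (mean 0.0449, 15 over 0.1), against a mean of -0.0219 for others, and 9 of 18 arrays correlated best with their own number, a hint from the data and not the design. With only the groups compared, which lowers the residual degrees of freedom, they were 11 at 66, 826 at 527.1, 0 between 1054.2 and 527.1 (where Akr1b7 also did not pass) and 91 between 1054.2 and 66 mg/kg.

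With dim probe sets left out the count was 46 at 132 mg/kg and 2 between the highest doses, and r was 0.396 at 66 and 0.603 at 527.1 mg/kg. Quantile normalization again gave 50 at 132 and 221 at 263.6, centred medians 75 at 263.6, and a variance trend with robust moderation 12 at 132 mg/kg. A change of at least 1.5-fold, by its construction, left 286 at 527.1 and 518 at 1054.2 mg/kg. Dose in mg/kg gave 879 for the trend. The covariate gave 839 at 527.1 and 8 between the highest doses, and with replicates 1 or 3 of 132 mg/kg left out 8 and 4. Without the 2 arrays of highest 3' to 5' difference 11 passed at 132 and 56 at 263.6 mg/kg. Lists called with an estimated correlation were 0, 0, 1, 1 and 4 from the lowest dose up, with fry 1, 2 and 6 at 66, 132 and 527.1, and by the exact test 3 and 9 at 66 and 132 mg/kg. With the same 5 controls on both sides r was 0.563, 0.529, 0.550 and 0.689.

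Among all 56 splits of the 8 arrays, the real split alone called the most probe sets at 132 mg/kg (real 21, highest other 5) and 263.6 mg/kg (133 and 6). It also did so at 527.1 (520 and 1) and 1054.2 mg/kg (1024 and 1), and over 100 splits for the trend (1569 and 414). The smallest share that 56 splits allow is 1 of 56, and several counts were ranked, so these ranks go against chance without excluding it. The count at 132 mg/kg was 6 without its replicate 1 and 1482 without its replicate 3. At 66 mg/kg 2 of the 56 splits, the real one included, call 2 probe sets (real 2, highest other 2), so the real count does not exceed what chance gave, and it is 0 without 66 mg/kg replicate 1. For the contrasts of 1054.2 with 527.1 (real 4, highest other 0) and with 66 mg/kg (real 154, highest other 0), 10 splits are too few. For lists the real split called the most only at 132 mg/kg (1 split, real 14, highest other 12), where 0 lists held with an estimated correlation. Counting the real split, 3 splits called as many or more at 66 mg/kg (11 and 12). These were 5 at 263.6 (11 and 13), 6 at 527.1 (10 and 12) and 4 at 1054.2 mg/kg (13 and 15). Chance is not excluded for the lists at any dose. Signal over background limits dim probe sets: 15521 lay at or above log2 6.37.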

Other observations

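The genes of this part fall outside the rule for naming genes, and they and their tests, the contrasts of Myc between doses included, were chosen only after the result was seen.

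At 1054.2 mg/kg several further genes of known function in liver were past the threshold, with 3 of 3 rats on the side given. Mt2A, a metallothionein, was 1.56 ± 0.30 log2 higher (SE, adjusted p = 0.00584), the ceramide synthase gene Cers6 1.68 ± 0.19 (adjusted p = 3.41e-05), the sulfotransferase gene Sult2a6 1.45 ± 0.19 (adjusted p = 1.40e-04) and Alas1, of haem synthesis, 1.07 ± 0.21 (adjusted p = 0.00607). Apoa4 (-1.43 ± 0.21, adjusted p = 4.93e-04), Fabp5 (-1.41 ± 0.22, adjusted p = 7.84e-04), the transcription factor gene Foxa3 (-1.27 ± 0.21, adjusted p = 0.00152) and Serpina7, the thyroxine-binding globulin gene (-1.59 ± 0.31, adjusted p = 0.00606), were lower. Without 1054.2 mg/kg replicate 3, Alas1 (0.0721) and Serpina7 (0.0635) did not pass. Both probe sets of the organic anion transporter Slc22a8 were lower (-1.40 and -1.39). Of 3 probe sets of Egfr, 2 were lower (-1.17 and -1.10) and the third, at -0.12, did not pass.

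Myc was higher than in controls by 1.83 log2 at 66 mg/kg and by 1.94 at 1054.2 mg/kg, and by 0.64, 0.44 and 0.68 at 132, 263.6 and 527.1 mg/kg (adjusted p = 0.235, 0.496 and 0.177). Its level at 66 mg/kg exceeded that at 132, 263.6 and 527.1 mg/kg by 1.19 ± 0.27, 1.39 ± 0.27 and 1.15 ± 0.27 (SE, n = 3 against 3), with adjusted p of 0.991, 0.112 and 0.121 over all probe sets, so these differences did not pass. Aacs and Insig1, lower at 132 mg/kg by log2 changes of -1.08 and -1.66, had changes of 0.47 and 0.26 at 1054.2 mg/kg that did not pass (adjusted p = 0.222 and 0.753); the difference between those doses was not tested.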
